A study of Danio rerio with 9 samples.

How the data were processed

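RNA sequencing libraries were made from cells sorted out of dissociated trunks of 72 hours post fertilization zebrafish. The labels name 3 groups with 3 samples each. Schwann cells, the glia of peripheral nerves, came from fish carrying a foxd3:mCherry gene trap and a sox10:mEGFP transgene. Cells of the oligodendrocyte lineage, the myelinating glia of the central nervous system and their precursors, came from fish carrying olig2:dsred and sox10:megfp transgenes. Neurons came from fish carrying an nbt:dsred transgene. RNA from 1750 ± 750 sorted cells per sample was purified on micro columns and amplified with a SMART-Seq v4 ultra low input kit, per the labels' protocols. Such libraries hold PCR copies without molecular identifiers, so counts are not independent molecules, and every floor given covers counting error only.

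Per the file headers, each deposited file lists a transcript ID, a transcript length, an effective length and an estimated count, which need not be a whole number, for each of 52216 zebrafish transcript IDs. The deposited lengths and effective lengths are in bases and differ from counts in kind, and they were used for TPM and for an offset. The submitters' processing notes list FastQC, Trimmomatic, Bowtie2 2.1.0, RSEM 1.2.15 and the genome build danRer10, without their order or roles. Which program wrote the deposited estimated counts, and the annotation release, are not given in the sources used here. Estimated counts divide reads between isoforms and near-identical genes, so the level of 1 transcript ID can carry reads from another. A total of 8317 transcripts, 21.5% of those with any count, held whole numbers in every library within a tolerance of 1e-06, and they took 21.3% to 24.5% of the counts of a library.

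Transcript IDs were looked up in a table of 29201 genes and in another of 49597 genes, and 0 IDs matched, because those tables list gene IDs and RefSeq accessions. The files do not pair transcript IDs with gene names, so counts were not summed per gene and the test was run per transcript ID, which was the stated fallback. The 37 gene lists fixed in advance, the marker genes and the reporter genes foxd3, sox10 and olig2 were not analysed here for the same reason.

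Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Transcripts were filtered with filterByExpr by group, which kept 23408 and left out 28808. Libraries were scaled by TMM factors, and a quasi-likelihood model with group as its only term was fitted to all 9 libraries together, so that the 3 groups shared an estimate of the spread with 6 residual degrees of freedom. The common biological coefficient of variation was 1.584. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 in a two-sided test. Levels are TMM-normalised CPM, counts scaled to a common library total, as mean ± SD over the 3 libraries of a group. Fold changes in text are ratios of mean CPM, and log2 fold changes are fitted values, with a standard error implied by the fitted value and its F statistic. Where every library of a group had no counts, the fold is a lower bound against 3 counts summed over that group. Single values per library were compared by exact two-sided permutation tests, and 3 libraries against 3 cannot give a p under 0.1. These tests formed a family of 30, adjusted by the Benjamini-Hochberg method. Libraries were compared by Spearman correlation of normalised levels over the tested transcripts. For equal-depth values every library was thinned at random to 7123174 counts.

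The rule for named transcripts, the tests, the lists and most alternatives were fixed before the data were examined. The rule took, per comparison and direction, the 8 called genes with the lowest adjusted p among those with an absolute log2 fold change of at least 1, a mean of at least 50 CPM in the higher group and no overlap between the libraries of both groups. Because it also asked for gene symbols, only 2 transcript IDs per direction are printed. The rule had 49 and 119 eligible transcripts in the comparison of both glial groups, 13 and 63 for Schwann cells and neurons, and 8 and 12 for the oligodendrocyte lineage and neurons. Transcripts chosen after their values were seen are marked as such.

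The alternatives were other scalings (DESeq2 size factors and upper-quartile factors), no filter, a filter of at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, limma on log2(TPM + 1) with a pseudocount of 1, an effective length offset, thinning to equal totals, only the groups compared in the fit, a replicate block, and leaving out each library in turn. Further settings were added after the data were seen. They used only transcripts with whole-number counts, at least 10 counts in every library of at least 1 group, a robust fit, only the compared groups on the same transcripts as the full fit, or all libraries but Schwann cells replicate 2 and oligodendrocyte lineage replicate 3. DESeq2 left 1863 adjusted p-values undefined in each comparison, and these were not counted.

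The pipeline was tested on simulated data with each transcript's mean over all 9 libraries, the real library totals and 23408 transcripts. Each transcript had the same dispersion in all 3 groups. Their unequal spread was thus not simulated, and the rates do not rank the comparisons. At the spread fitted to all 9 libraries together, 1024-fold changes were recovered for 26% of 50 transcripts in the Schwann cell and oligodendrocyte lineage comparison. The rate was 14% in the Schwann cell and neuron comparison and 12% in the oligodendrocyte lineage and neuron comparison, with 0 false calls in each. At that spread 64-fold changes were recovered for 0% in each of the 3 comparisons. With 0.1 of the dispersion, 64-fold changes were recovered for 98%, 98% and 96% in the same order, with 3, 3 and 4 false calls. Libraries of a group differed by chi-square values of 132.3 to 399.2 per degree of freedom over transcripts with at least 20 counts in the pair, so none was counted as a duplicate.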

Results

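The data were transcript abundance tables of 9 libraries from cells sorted out of 72 hours post fertilization zebrafish trunks, 3 each of Schwann cells, oligodendrocyte lineage cells and neurons. Summed estimated counts were 8502028, 7123251 and 11191844 in Schwann cells, 14572760, 15266878 and 11869510 in the oligodendrocyte lineage, and 17126213, 11439759 and 13646847 in neurons. Transcripts are given by ID because the files do not pair the IDs with gene names. Nothing in the labels says that the libraries of a group came from separate clutches or sorts, so p-values measure only the spread between these samples, which may be technical. Each population also came from fish carrying a different set of transgenes. Differences between groups, and the grouping of libraries, cannot be told apart from differences between those fish or their sorts.

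Neuron libraries held more transcripts than Schwann cell libraries, and a few transcripts took a larger share of their counts. At equal depth, 18281 ± 3309 transcripts had at least 1 count in Schwann cells (SD, n = 3), 20921 ± 2868 in the oligodendrocyte lineage and 24856 ± 2522.5 in neurons. Every neuron library lay above every Schwann cell library (exact permutation p = 0.1, the smallest possible, adjusted 0.231). Schwann cells replicate 3, at 22090, was close to neurons replicate 2, at 22866, while Schwann cells replicates 1 and 2 had 16644 and 16110. Schwann cells and the oligodendrocyte lineage overlapped (exact p = 0.3, adjusted 0.45), as did the oligodendrocyte lineage and neurons (exact p = 0.2, adjusted 0.333). The 10 most abundant transcripts of each library took 4.51% ± 0.738 of the counts in Schwann cells, 6.21% ± 2.61 in the oligodendrocyte lineage and 16.97% ± 0.980 in neurons. Neurons stood above each glial group in all 3 libraries (exact permutation p = 0.1 against each, the smallest possible, adjusted 0.231).

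**Figure D1:**
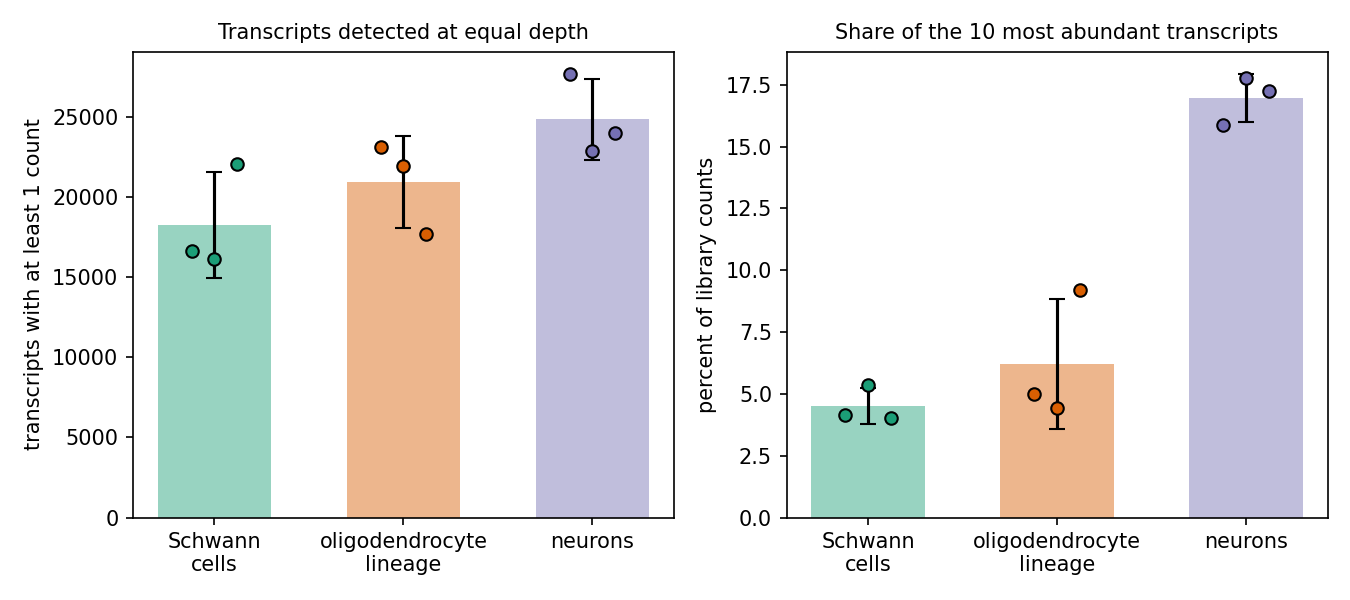
Left, transcripts with at least 1 count after thinning every library to the same total. Right, percent of library counts in the 10 most abundant transcripts. Bars are group means, error bars are SD (n = 3) and points are libraries, with neurons at 16.97% against 4.51% in Schwann cells and 6.21% in the oligodendrocyte lineage.

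Libraries grouped by sorted population. The mean Spearman correlation between libraries was 0.691 within neurons, 0.561 within the oligodendrocyte lineage and 0.45 within Schwann cells. Between groups it was 0.438 for the oligodendrocyte lineage with neurons, 0.376 for Schwann cells with the oligodendrocyte lineage and 0.374 for Schwann cells with neurons. Of the 280 ways to part the 9 libraries into 3 groups of 3, the sorted populations gave the highest mean correlation within groups, 0.567, with 0.526 for the next (exact permutation p = 0.00357, the smallest possible). The most similar library was of the same population for 8 of 9 libraries. The exception was Schwann cells replicate 3, which correlated at 0.498 with neurons replicate 1 and at most at 0.493 with another Schwann cell library. The spread between replicates was widest in Schwann cells, with a biological coefficient of variation of 1.983 against 1.599 in the oligodendrocyte lineage and 1.184 in neurons.

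**Figure D2:**
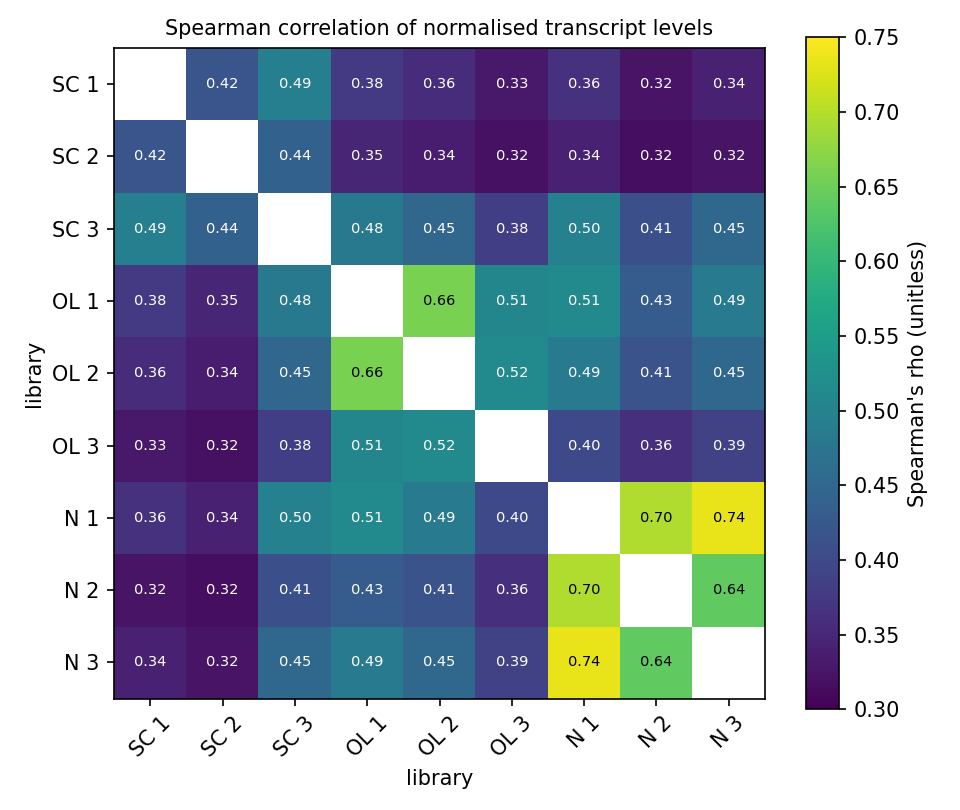
Spearman correlation (unitless, colour and number) of normalised transcript levels between each pair of the 9 libraries, for Schwann cells (SC), the oligodendrocyte lineage (OL) and neurons (N) with replicate numbers. Pairs of neuron libraries range from 0.641 to 0.735 and pairs of Schwann cell libraries from 0.419 to 0.493.

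The first comparison asked which transcripts differ between the glia of peripheral nerves and the oligodendrocyte lineage of the central nervous system. ENSDART00000010896.5 was at 955 ± 237 CPM in Schwann cells and 0.487 ± 0.50 CPM in the oligodendrocyte lineage (SD, n = 3 each), a 1964-fold difference, with 268 ± 65.1 CPM in neurons. ENSDART00000132405.3 was at 409 ± 38.1 CPM in Schwann cells, 0.144 ± 0.0636 CPM in the oligodendrocyte lineage and 14.0 ± 8.87 CPM in neurons. In the other direction, ENSDART00000113342.4 was at 488 ± 61.5 CPM in the oligodendrocyte lineage and 0.181 ± 0.0728 CPM in Schwann cells. ENSDART00000123216.2 was at 483 ± 158 CPM with no counts in Schwann cells, at least 4350-fold higher by counting error alone, against a floor of 3 counts over the group. Transcripts with at least 20 CPM in both other Schwann cell libraries had no counts in the third in 9.03% of cases. The true fold may therefore be smaller. Neurons also carried these oligodendrocyte lineage transcripts, at 266 ± 57.8 and 95.2 ± 16.5 CPM.

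In edgeR's quasi-likelihood test the Schwann cell transcripts had log2 fold changes of 10.93 (SE 1.02, adjusted p = 0.0138) and 11.37 (SE 1.18, adjusted p = 0.0141). ENSDART00000113342.4 had a log2 fold change of -11.33 (SE 0.80, adjusted p = 0.00263), and ENSDART00000123216.2 had an adjusted p of 0.0138. Of 23408 transcripts tested, 186 were called, 53 higher in Schwann cells and 133 lower, and 50 of the 186 had no counts in the lower group. Their fitted log2 fold changes had a median size of 10.72 and a smallest size of 1.19, and the median is no bound because it holds transcripts without counts in a group. An unadjusted p under 0.05 was reached by 4004 transcripts, where chance gives 1170.4. Every Schwann cell library lay above every oligodendrocyte lineage library for 5.69% of transcripts, and the reverse held for 11.2%, where chance gives 5% each. DESeq2 called 3350 transcripts, including all 186, and voom with quality weights called 511, sharing 156.

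Fits without 1 library tested 25689 to 27138 transcripts in place of 23408, because the filter was applied anew. Effects of the library and of the filter are thus mixed in all counts from such fits. Over these fits the count of 186 moved by over 1.5 times for each of the 9 libraries left out. It was 50, 123 and 379 without Schwann cells replicate 1, 2 and 3, then 105, 1 and 23 without oligodendrocyte lineage replicate 1, 2 and 3, and 13 without any one of the neuron replicates. Without oligodendrocyte lineage replicate 2, ENSDART00000010896.5, ENSDART00000132405.3 and ENSDART00000123216.2 lost their calls with edgeR adjusted p-values of 0.0567, 0.0763 and 0.0567, and ENSDART00000113342.4 passed. ENSDART00000010896.5 (0.0576) and ENSDART00000123216.2 (0.0941) also lost their calls when only both glial groups were fitted, where on the same 23408 transcripts the first passed (0.0485) and the second did not (0.0829), and ENSDART00000132405.3 (0.0662) without Schwann cells replicate 2 and oligodendrocyte lineage replicate 3 together.

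The second comparison set Schwann cells against neurons. ENSDART00000102715.4 was at 831 ± 260 CPM in Schwann cells and 63.4 ± 10.7 CPM in neurons (SD, n = 3 each), 13.1-fold higher. ENSDART00000161276.1 was at 1081 ± 33.5 CPM in Schwann cells and 167 ± 12.3 CPM in neurons, 6.48-fold higher. Both were also abundant in the oligodendrocyte lineage, at 976 ± 203 and 1587 ± 394 CPM. ENSDART00000161276.1 belonged to a set of 48 abundant transcripts linked, in part through chains of pairs, by levels that varied together between libraries of a group. Among transcripts lower in Schwann cells, ENSDART00000113342.4 was at 0.181 ± 0.0728 CPM there and 266 ± 57.8 CPM in neurons, and ENSDART00000097982.5 was at 0.512 ± 0.153 CPM there and 519.5 ± 142 CPM in neurons, with 0.480 ± 0.0750 CPM in the oligodendrocyte lineage.

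In edgeR's quasi-likelihood test ENSDART00000102715.4 had a log2 fold change of 3.71 (SE 0.436, adjusted p = 0.0211) and ENSDART00000161276.1 one of 2.70 (SE 0.327, adjusted p = 0.0234). The transcripts lower in Schwann cells had log2 fold changes of -10.45 (SE 0.777, adjusted p = 0.00416) and -9.95 (SE 0.859, adjusted p = 0.00791). A total of 83 transcripts were called, 13 higher in Schwann cells and 70 lower, 16 of them without counts in the lower group. An unadjusted p under 0.05 was reached by 3747 transcripts. All Schwann cell libraries lay above all neuron libraries for 6.37% of transcripts and below them for 19.1%, where chance gives 5% each. DESeq2 called 3161 transcripts, sharing 81 of the 83, and voom with quality weights called 1677, sharing 80.

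The count of 83 became 14 and 25 without Schwann cells replicate 1 and 2, then 14, 4 and 38 without oligodendrocyte lineage replicate 1, 2 and 3, and 2, 1 and 1 without neurons replicate 1, 2 and 3. ENSDART00000102715.4 and ENSDART00000161276.1 lost their calls without oligodendrocyte lineage replicate 2 and without each neuron library (edgeR adjusted p from 0.0629 to 0.158) and when only Schwann cells and neurons were fitted (0.0521 each), as did ENSDART00000161276.1 without Schwann cells replicate 1 (0.0536) and ENSDART00000097982.5 without each neuron library (0.0621 to 0.0817).

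The third comparison set the oligodendrocyte lineage against neurons. ENSDART00000112979.2 was at 4348 ± 762 CPM in the oligodendrocyte lineage and 115 ± 67.9 CPM in neurons (SD, n = 3 each), 37.7-fold higher, with 1501 ± 717 CPM in Schwann cells. ENSDART00000102715.4 was 15.4-fold higher in the oligodendrocyte lineage than in neurons, at the levels given above. ENSDART00000011943.6 was at 446 ± 69.4 CPM in neurons against 0.124 ± 0.0533 CPM in the oligodendrocyte lineage and 0.961 ± 0.479 CPM in Schwann cells. ENSDART00000097982.5 was 1084-fold lower in the oligodendrocyte lineage than in neurons.

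In edgeR's quasi-likelihood test the transcripts higher in the oligodendrocyte lineage had log2 fold changes of 5.24 (SE 0.558, adjusted p = 0.0191) and 3.94 (SE 0.441, adjusted p = 0.0191), and those higher in neurons had -11.72 (SE 1.07, adjusted p = 0.013) and -10.05 (SE 0.860, adjusted p = 0.013). A total of 20 transcripts were called, 8 higher in the oligodendrocyte lineage and 12 lower, and 0 of them lacked counts in the lower group. An unadjusted p under 0.05 was reached by 2669 transcripts. All oligodendrocyte lineage libraries lay above all neuron libraries for 9.43% of transcripts and below them for 15.7%, where chance gives 5% each. DESeq2 called 2034 transcripts, sharing 19 of the 20, and voom with quality weights called 2130, sharing all 20.

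The count of 20 became 31 and 58 without Schwann cells replicate 1 and 2, then 1 and 10 without oligodendrocyte lineage replicate 2 and 3, and 0, 1 and 0 without neurons replicate 1, 2 and 3, where edgeR gave 2353, 2633 and 2504 transcripts at an unadjusted p under 0.05. All 4 named transcripts lost their calls without oligodendrocyte lineage replicate 2 and without each neuron library (edgeR adjusted p from 0.0586 to 0.172), and ENSDART00000112979.2 also without Schwann cells replicate 2 and oligodendrocyte lineage replicate 3 together (0.0585).

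**Figure D3:**
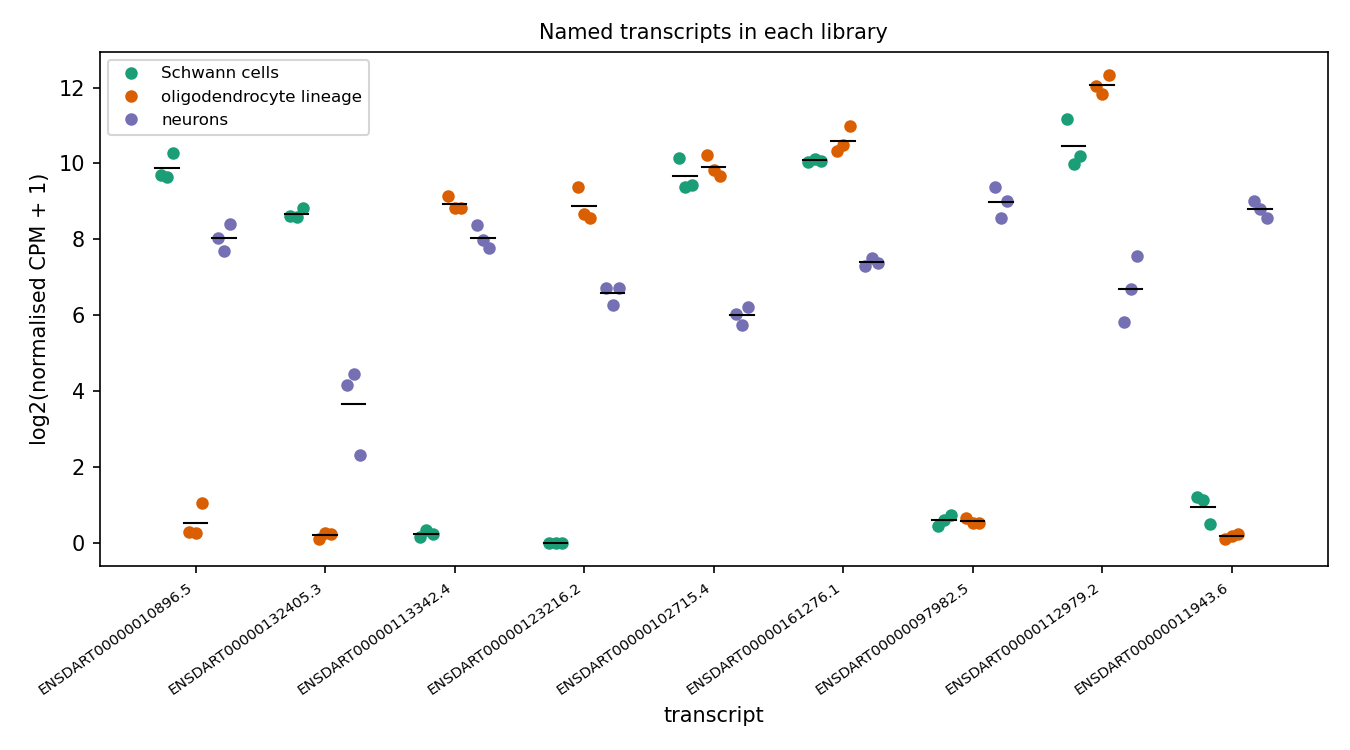
Normalised levels, as log2(CPM + 1), of the transcripts named in the pairwise comparisons. Points are libraries (3 per group) and lines are group means. ENSDART00000123216.2 has no counts in any Schwann cell library and a mean of 483 CPM in the oligodendrocyte lineage.

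The scaling of the libraries moved the share of calls in each direction under upper-quartile factors and less so under DESeq2 size factors. Over all tested transcripts the median log2 fold change was -0.205 for Schwann cells against the oligodendrocyte lineage, -0.314 for Schwann cells against neurons and -0.0622 for the oligodendrocyte lineage against neurons. With upper-quartile factors these medians were 0.105, 0.129 and 0.0617, and with DESeq2 size factors -0.00912, -0.109 and -0.0375. The share of called transcripts that were higher in the first group moved from 28.5% to 39.3%, from 15.7% to 29.2% and from 40% to 50% with upper-quartile factors, the last of these over 8 calls, 4 in each direction. With DESeq2 size factors in edgeR the shares were 31.4%, 19.1% and 40%. The tool and the groups fitted moved the shares as well. They were 38.3%, 19.7% and 22% with DESeq2 itself and 38.7%, 16.7% and 22.8% with voom. In edgeR with only the compared groups, on the same transcripts, they were 42.9%, 30.8% and 24.6%. The transcripts named by the rule differed by far more than the shifts in median log2 fold change between scalings. Their kept direction under every scaling tried thus follows from their choice.

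The tool and the samples in the fit changed both the number of calls and the order of the comparisons. When only the compared groups were fitted, edgeR called 6 transcripts between Schwann cells and the oligodendrocyte lineage, 15 between Schwann cells and neurons and 278 between the oligodendrocyte lineage and neurons. On the same 23408 transcripts as in the fit of all 9 libraries it called 7, 13 and 175.

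**Figure D4:**
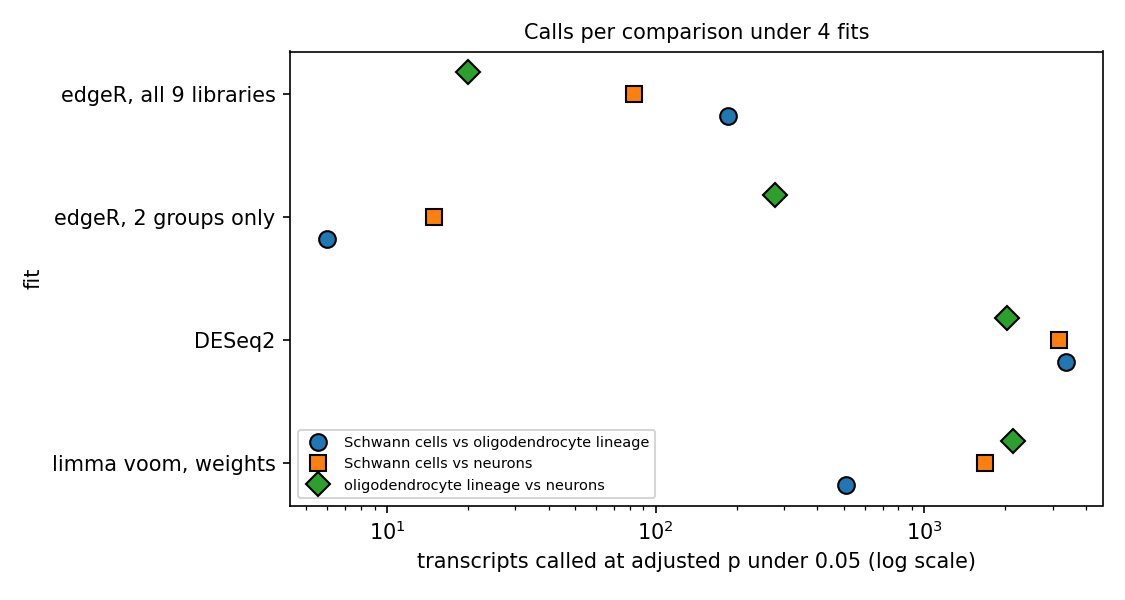
Transcripts called at an adjusted p under 0.05 (log axis) in each of the 3 comparisons under 4 fits. The fit of all 9 libraries with edgeR gives 186, 83 and 20, and voom with quality weights gives 511, 1677 and 2130, in the opposite order.

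Transcripts higher in a population than in both others were then counted. Schwann cells had 1, ENSDART00000043298.7, at 5363 ± 1080 CPM against 2359 ± 83.4 CPM in the oligodendrocyte lineage and 1868 ± 214 CPM in neurons (edgeR adjusted p = 0.0398 and 0.0311), named after its values were seen. Neurons had 6, with mean levels from 144.1 to 30800 CPM in neurons, among them ENSDART00000097982.5 and ENSDART00000011943.6. The oligodendrocyte lineage had 0 with edgeR, while 210 passed an unadjusted p under 0.05 in both comparisons, and DESeq2, voom and limma on log2(TPM + 1) gave 139, 88 and 153. At that unadjusted threshold Schwann cells had 140 and neurons 758. No chance count was worked out for the unadjusted counts, which join comparisons that share libraries, so their excess is not known. The counts for independent lists below apply only to edgeR's adjusted calls. DESeq2 gave 130 for Schwann cells and 622 for neurons. Independent lists would give 0.0294 transcripts for Schwann cells, 0.0455 for the oligodendrocyte lineage and 0.0359 for neurons, but each count joins comparisons that share the 3 libraries of that population, so the lists are not independent and part of any excess may come from those libraries. ENSDART00000043298.7 passed both tests without Schwann cells replicate 2, and without any other single library its edgeR adjusted p against the oligodendrocyte lineage was 0.0768 to 0.152, with 0.154 without a filter and 0.124 when only those groups were fitted. The Schwann cell count was 0 without Schwann cells replicate 1, oligodendrocyte lineage replicate 1 or 2, or neurons replicate 2 or 3. It was 1 without Schwann cells replicate 3, oligodendrocyte lineage replicate 3 or neurons replicate 1, but there the transcript was a different one. The neuron count was 1 and 2 without oligodendrocyte lineage replicate 2 and 3 and 0 without any one neuron library, and the oligodendrocyte lineage count was 1, 7 and 2 without Schwann cells replicate 1, 2 and 3 and 1 without neurons replicate 2.

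Both glial groups shared 7 transcripts that were higher than in neurons. Among them were ENSDART00000102715.4 and ENSDART00000112979.2, 2 of the 7 belonged to the set of 48 that varied together between libraries of a group, and their mean levels ranged from 321.5 to 5148 CPM in Schwann cells and from 427 to 6788 CPM in the oligodendrocyte lineage against 13.3 to 1316 CPM in neurons. The 6 transcripts lower in both glial groups are the same 6 already counted as higher in neurons than in both others. Both comparisons use the same neuron libraries, and 10 simulations of unchanged groups against them gave a mean of 0 shared calls in each direction. The test made 0 false calls on simulated unchanged transcripts at this spread, so that 0 does not measure what shared libraries add to the 7 and the 6. Independent lists would give 0.00444 shared higher transcripts. Across transcripts, which are not independent replicates, the fold changes of both comparisons correlated at r = 0.339 against 0.0838 in the simulations, with a covariance of 4.42 against 0.31 and a difference of 4.11. The simulations may not hold all the noise that shared neuron libraries add, so this difference does not measure a shared change. The 3 neuron libraries cannot be split into parts of at least 2, so part or all of the excess may come from the shared controls. The count of 7 became 2 without Schwann cells replicate 1, then 2, 0 and 2 without oligodendrocyte lineage replicate 1, 2 and 3 and 0 without any one neuron library, and DESeq2 gave 229.

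A few transcripts dominated the neuron libraries. With a threshold set after the values were seen, 4 transcripts exceeded 10000 CPM of the unscaled library total in every neuron library and 0 did so in either glial group. These 4 took 12.9% ± 1.09 of neuron counts, 0.129% ± 0.119 of Schwann cell counts and 0.199% ± 0.164 of oligodendrocyte lineage counts (SD, n = 3), and no test of this sum is given because the threshold itself picked them for their level in neurons. ENSDART00000168815.1 took 2.82% ± 0.27 of neuron counts, and its log2 fold change was -10.42 for Schwann cells against neurons (edgeR adjusted p = 0.0182) and -6.87 for the oligodendrocyte lineage against neurons (edgeR adjusted p = 0.0468). The first call was lost without Schwann cells replicate 1 (0.0518) or 2 (0.0501), without each neuron library (0.0671 to 0.0797) and without Schwann cells replicate 2 and oligodendrocyte lineage replicate 3 together (0.0617). The second was lost without oligodendrocyte lineage replicate 1 (0.0587) or 3 (0.121), without each neuron library (0.158 to 0.172), in the robust fit (0.0573) and without the same pair of libraries (0.12). ENSDART00000009393.7 took 7.91% ± 0.74 of neuron counts, 0.116% ± 0.11 of Schwann cell counts and 0.111% ± 0.11 of oligodendrocyte lineage counts, and edgeR did not call it (adjusted p = 0.0548 and 0.0776), while DESeq2, voom, limma on log2(TPM + 1) and edgeR without a filter called it in both comparisons (adjusted p from 2.36e-06 to 0.0136). The other 2 took 1.13% ± 0.082 and 1.03% ± 0.013 of neuron counts. EdgeR called the first of these against Schwann cells (adjusted p = 0.0259) and not against the oligodendrocyte lineage (0.0621), and the second against neither (0.0755 and 0.195), while voom and limma on log2(TPM + 1) called both against each glial group. That edgeR call was lost without Schwann cells replicate 1 (adjusted p = 0.0518), oligodendrocyte lineage replicate 2 (0.0584) or any one neuron library (0.111 to 0.115) and when only those groups were fitted (0.0644). By contrast, without Schwann cells replicate 1 edgeR called the transcript at 1.03% of neuron counts against Schwann cells (adjusted p = 0.00963) and the oligodendrocyte lineage (0.0219).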

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

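The whole-number, 10-count, robust and 2-library settings and the fit of the compared groups on the same transcripts were chosen after the data were seen; the other alternatives were fixed before. Counts are listed for Schwann cells vs oligodendrocyte lineage, Schwann cells vs neurons and oligodendrocyte lineage vs neurons (186, 83 and 20 transcripts as reported), then for transcripts higher in Schwann cells, the oligodendrocyte lineage or neurons than in both others (1, 0 and 6) and higher in both glial groups than in neurons (7). DESeq2 size factors in edgeR and an effective length offset moved no count by over 1.5 times. Upper-quartile factors gave 107, 48 and 8, with 3 for neurons and 4 for both glial groups. Without a filter, Schwann cells vs neurons gave 144 and oligodendrocyte lineage vs neurons 65, with 3, 7 and 20 for the single populations. At least 10 CPM in 3 libraries gave 363, 344 and 70, with 12, 7 and 18. DESeq2 gave 3350, 3161, 2034, 130, 139, 622 and 229, voom with quality weights 511, 1677, 2130, 87, 88, 788 and 54, and limma on log2(TPM + 1) 887, 1797, 1270, 92, 153, 750 and 53. Thinning to equal totals gave 3 for neurons. Only transcripts with whole-number counts gave 52 and 42 for both Schwann cell comparisons, where fewer transcripts were tested, with 3 for Schwann cells, 3 for the oligodendrocyte lineage and 1 for both glial groups. At least 10 counts in every library of a group gave 455, 719 and 91, with 11, 9 and 24. A robust fit gave 2 for Schwann cells and 3 for neurons. Without both Schwann cells replicate 2 and oligodendrocyte lineage replicate 3, the Schwann cell comparisons gave 15 and 22, with 0 for Schwann cells, 1 for the oligodendrocyte lineage and 3 for both glial groups. Fitting only the compared groups gave 6, 15 and 278, and 7, 13 and 175 on the same transcripts. Leaving out each library in turn gave 1 to 379, 1 to 118, 0 to 58, 0 to 1, 0 to 7, 0 to 8 and 0 to 6. Each of those fits had fewer samples and more tested transcripts. Apart from these changed sets of transcripts or samples, and the tests of library depth and shared spread below, the cause was not tested.

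With the replicate block, edgeR called 2, 0 and 0 transcripts in the 3 comparisons, where 2340, 2846 and 2116 passed an unadjusted p under 0.05, and 0 in each of the 4 intersections, where 129, 189, 679 and 130 passed in both comparisons. The block is not part of the design. Of 9 pairs of libraries with the same number, 0 had deviations from their group means that correlated above 0.1 (from -0.036 to 0.028), and 2 of 9 libraries correlated best with a library of their own number. Each transcript named by the rule kept its direction in all 295 checks, and in 50 of them its adjusted p rose above 0.05. The rule took only transcripts without overlap between the compared groups, so the kept direction was largely fixed by that choice and is no test. Leaving out gene lists, the list tests and their alternatives were not run, because they need gene names, and testing each transcript ID is the analysis reported. Thinning to the smallest total left 170, 77 and 19 calls. At the spread fitted to all 9 libraries together, the same in each simulated group, edgeR recovered the largest simulated changes for 26%, 14% and 12% of transcripts. It recovered 64-fold changes for 0% at that spread and for 98%, 98% and 96% with 0.1 of the dispersion. In the simulations the spread thus limited its calls. DESeq2 called many more on the real counts, so the number of calls depends on the tool. Why the tools differ was not tested.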

Other observations

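The tests of read depth, of reads split between isoforms, of few starting molecules, of the shared spread on the same transcripts and of the library total were chosen only after the results were seen.

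Transcript lengths were compared between the groups. The count-weighted median transcript length was 3063 ± 103 bases in neurons, 2824 ± 123 in Schwann cells and 2797 ± 135 in the oligodendrocyte lineage (SD, n = 3, exact permutation p = 0.1 for neurons against each, the smallest possible, adjusted 0.231 over 30 tests). Without the 10 most abundant transcripts of each library the medians were 2935, 2867 and 2862 (exact p = 0.5 and 0.7 for neurons against Schwann cells and the oligodendrocyte lineage). Of the transcripts called between Schwann cells and neurons, those higher in neurons had a median length of 3231.5 bases and those higher in Schwann cells one of 1950, against 2264 for all tested. The medians were 2353 and 2187 for transcripts higher in neurons and in the oligodendrocyte lineage, and 2857 and 2909 for those higher in Schwann cells and in the oligodendrocyte lineage, so long called transcripts were not particular to neurons.

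Transcripts abundant in 2 libraries of a group were at times absent from the third. Among 45855 such cases with at least 20 CPM in both other libraries, 2117 had no counts, 9.03% of cases in Schwann cells, 4.85% in the oligodendrocyte lineage and 1.76% in neurons, with the highest shares in Schwann cells replicate 2 (13.6%) and oligodendrocyte lineage replicate 3 (9.56%). Counting error at these depths gives 4.86e-64 cases, which argues against read depth, and transcripts with whole-number counts in both other libraries had 0.824 times the share of the others (4.03% against 4.88%), which argues against isoform splitting as the whole cause. The share fell from 7.02% at 20 to 50 CPM to 0.535% at 200 CPM or more, a ratio of 0.0761, but most causes would make zeros rarer at higher levels, so the fall does not single any out, and the logarithm of the share changed 1.97-fold over a 17.8-fold range of mean level, far less steeply than sampling of molecules at one rate gives. Few starting molecules at rates that differ between libraries and transcripts, and differences in cell makeup between sorts of a group both stay open, and no biological explanation was tested.

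The order of the 3 comparisons by number of calls was opposite in edgeR (186, 83 and 20) and in voom with quality weights (511, 1677 and 2130). Thinning to equal totals left 19 calls between the oligodendrocyte lineage and neurons, which argues against library depth. Fitting only those groups gave 278, and 175 on the same 23408 transcripts, while leaving out a single Schwann cell library gave 31, 58 and 22. The 175 is consistent with the hypothesis that the spread shared with the Schwann cell libraries may hold down that count. In both Schwann cell comparisons the calls fell instead, from 186 to 7 and from 83 to 13 on the same transcripts. The count of 186 also fell to 13 without any one neuron library, the group with the smallest spread. The spread shared by all groups may thus raise these counts, though fewer libraries or, without a neuron library, more tested transcripts may lower them as well. How far the populations themselves differ stays open and was not tested by these counts.

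Among 172 transcripts with a mean of at least 500 CPM, 48 were linked in a set by levels that varied together within groups. Pairs were linked at r above 0.9 and the set was joined through chains of pairs, so its members need not all correlate at that level. The set took 4.12% to 14.58% of counts, with 14.58% in oligodendrocyte lineage replicate 3 and 9.88% in Schwann cells replicate 2. The largest such set in 100 permutations within groups held 34 transcripts and the median one 14, which argues against chance. The differences of the set between group means spread by 0.772 on the log2 scale, at percentile 2.46 of 10000 random sets of like abundance (median 1). A set from one source of RNA at different shares could give this. The random sets were matched for abundance and not for varying together in every group. That choice may itself favour small differences, so the percentile does not decide and one source stays open. The mean level of the set fell with the library total within groups (r = -0.825, exact permutation p = 0.0185, rho = -0.833, exact permutation p = 0.0648, and r = -0.752 without Schwann cells replicate 2 and neurons replicate 1), so the total stays open as well. The transcripts are not paired with gene names, 5 of the 48 were called in a comparison, ENSDART00000161276.1 among them, and no biological explanation was tested.

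For each pairwise comparison the 6 libraries allow 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with calls in each case, 186, 83 and 20, and the highest other split gave 0. For transcripts higher in a population than in both others, the real grouping gave 7 in total. Of 50 splits drawn from 280, 1 gave as many, the real one, and the highest other gave 1. That share is the smallest that 50 splits can give, and it shows only that the calls followed the labels over all 9 libraries. Every other split mixes populations within a group, which can widen the spread. Few calls there thus do not show what made the labelled groups differ. The total moved with single libraries left out, where more transcripts were also tested. It was 12 and 11 without Schwann cells replicate 2 and 3, then 4, 1 and 3 without oligodendrocyte lineage replicate 1, 2 and 3, and 1, 1 and 0 without neurons replicate 1, 2 and 3.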
